A study of Vitis vinifera with 2 samples.

How the data were processed

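Per the labels, total RNA was extracted from somatic embryos of the cultivar Brachetto by a rapid CTAB method, small RNA libraries were made with an Illumina TruSeq Small RNA kit, PARE libraries followed a published protocol, and both were sequenced on an Illumina HiSeq. There were 2 samples, 1 small RNA library and 1 PARE library, with no replicate. The groups are the kinds of library, and they measure different molecules of the same tissue, so they were set side by side and never tested against each other.

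The small RNA sample has a miRNA family profile, a list of predicted loci and their hairpins. Per the file headers, the profile came from miRProf, which matched reads to mature miRBase sequences without mismatches, kept the best matches, and combined organisms and variants. The profile gives read counts per sequence and family, which the authors deposited without normalisation, and RPM values, scaled to the 8489420 filtered reads, per the file headers. The header records 28573066 input reads and 8489497 after a length filter, so 70.3% of the reads were removed by length. The length limits and the miRBase release were not given in the sources used here. A column headed as genome matches differed between families for 1 sequence and was not interpreted. The profile counts 4 sequences in 2 families each. Family totals summed to 3363634 reads and distinct sequences to 3347254, and shares were taken of the latter.

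The deposited list of predicted loci gives read counts of each mature sequence, genomic positions, hairpin length, minimum free energy and star sequences. The file is named after the tool miRCAT. Its version, its parameters and the genome build were not given in the sources used here, so coordinates are on the authors' unnamed build. Most cells of 2 deposited columns (hairpin GC content and adjusted energy) had lost their decimal mark. Energy per 100 nt was therefore recomputed from the energy and the hairpin length, and GC content from the hairpin sequence. All 317 loci matched a hairpin record.

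The PARE list holds 1 record per small RNA and reported cleavage site. Each gives the transcript, a category from 0 to 4, the position, a p-value, read counts at the site, an alignment score and the duplex. The p-value and the category and alignment score are those of the authors' caller, and they were used only to describe, rank and filter. The deposited list goes up to a p-value of 0.1 and a score of 4.5. The caller, its version and the transcript annotation were not given in the sources used here. Of its 256397 lines, 105 were blank and were not analysed here, and the last record is cut short. The small RNA could not be read in 20 records and the target in 397. The deposited read counts of small RNAs equal those of the profile for shared sequences. The normalised columns had lost the decimal mark in many cells. Library totals were taken as the median over sites of 1 read (PARE, 1192366 reads) and over records of under 5 small RNA reads (19438825 reads). The latter total differs from that of the profile, for a reason that the sources used here do not give.

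A small RNA of the PARE list was assigned to a miRNA family where its sequence was identical to a profile sequence, and a locus was called known by the same rule. Shares have exact Clopper-Pearson intervals at 95%, and a count of 0 allows 3 counts, or 0.353 RPM. Medians of known loci were set against 10000 random sets of loci of the same size. Differences between a small RNA and profile sequences were edit distances with overhanging profile ends free, at most 2. A sequence was nested where it lay within a profile sequence, or contained one, with at least 18 nt. Target sequences were translated in 3 frames. The work used Python 3.11.15, pandas 2.3.3, scipy 1.17.1, Biopython 1.88, edlib 1.3.9 and matplotlib 3.10.9.

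The statistics were first tested on simulated data, in which loci were drawn singly, so loci that share a mature sequence were not modelled. With 63 of the 317 loci drawn at random, the median of the set lay outside the central 95% of random sets in 3 of 100 runs with no difference, in 63 of 100 at a fold of 2 and in 100 of 100 at a fold of 4. All 200 simulated variants of profile sequences with 2 substitutions were found within 2 differences, and none of 200 shuffled sequences was.

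Before the data were examined, the named items were fixed as the 20 families with the most counts, the 15 most abundant loci, the 5 most abundant unmatched loci, the 15 category 0 sites with the most reads (1 per transcript), and the best site of each family on a fixed list of conserved miRNA and target modules. The broader target classes were grouped from that list afterwards. Alternatives fixed at the same time were the RPM column, single mature sequences, a minimum of 10 counts, distinct sequences, lengths of 20 to 22 nt, loci with a star, stricter categories, caller p-values of at most 0.01, scores of at most 3, distinct sites, and the leading family left out. A further 5 alternatives, on nested sequences, variants of profile sequences and fragments of 1 position, were added after the data were seen.

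Transcripts carry VIT identifiers that the files do not pair with gene names. None of the 4196 matched the gene table used here (assembly ASM3070453v1), so targets are described by chromosome, transcript position and miRNA family. Whether a site lies in a gene of the known target class, and counts of transcription factor, silencing, embryogenesis or transposon genes, could not be taken from annotations and were not analysed here. No genome was used here, so the position of loci relative to genes and to transposable elements was not analysed here either.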

Results

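Small RNAs and 5'-uncapped mRNA fragments were sequenced from somatic embryos of the grapevine (Vitis vinifera) cultivar Brachetto, embryos that form in culture from immature anthers. There were 2 libraries, 1 of each kind. The small RNA library entered the family profile with 28573066 reads of 1663530 distinct sequences, of which 8489420 reads (29.7%) passed the profile's filters. The other library was made by parallel analysis of RNA ends (PARE), which captures uncapped 5' ends such as those left when a small RNA directs cleavage of an mRNA. Its deposited normalised values correspond to a total of 1192366 reads. Neither library had a replicate, so the libraries were not tested against each other and no p-value was computed. Intervals are exact (Clopper-Pearson) 95% binomial intervals, and they cover counting error only, since amplified reads are not independent molecules. The labels give as the aim the regulatory non-coding RNAs of plant somatic embryos.

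The miRNA complement of the embryos was dominated by miR166, the family known to target the class III HD-ZIP transcription factors that set organ polarity. It had 2606778 reads, 77.9% of the 3347254 profile reads (95% interval 77.8% to 77.9%), or 307062 reads scaled to the filtered total (RPM). The next families were miR159, known to target GAMYB-type MYB genes, with 256217 reads (7.65%, 7.63% to 7.68%), and miR396, known to target growth-regulating factors, with 252629 reads (7.55%, 7.52% to 7.58%). miR166 thus had 10.2 times the reads of miR159, and these 3 families together held 93.1% of the profile reads. Counted as single mature sequences instead of families, the leading miR166 sequence alone held 58.4%.

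Below these, miR168, which targets the silencing effector AGO1, had 66445 reads (1.99%), and miR319, which targets TCP genes, had 48618 (1.45%). miR167, which targets the auxin response factors ARF6 and ARF8, had 40260 reads (1.20%), and miR398, which targets copper/zinc superoxide dismutases, had 29504 (0.881%). miR156 and miR157, both known for SPL targets, had 18976 and 12761 reads, 12686 of them from 1 sequence (TTGACAGAAGATAGAGAGCAC) that the profile counts in both families. With a nested 20-nt sequence of the predicted loci added, chosen after the data were seen, miR156 had 39172 reads. miR399, which targets the phosphate regulator PHO2, had 13571 reads. From rank 11 to rank 20 the counts fell from 3147 reads for miR162, which targets DCL1, through miR171 (2785), miR165 (2004), miR170 (1624), miR2118 and miR390 (1421 each), miR408 (920), miR393 (778) and miR172 (482), to 432 for miR164, known for NAC targets. All reads of miR170 came from TATTGGCCTGGTTCACTCAGA, also counted in miR171, and 1995 of the miR165 reads came from TCGGACCAGGCTTCATCCCCC, also counted in miR166. miR160, known for ARF10, ARF16 and ARF17, stood just below with 409 reads.

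Grouped by the target classes of the conserved families, the 13 detected families under transcription factors held 95.2% of the profile reads (95.2% to 95.2%). The families known for auxin response factors, miR167 and miR160, were counted under auxin and not in this group. RNA silencing families (miR168, miR162, miR403) held 2.09% (2.07% to 2.10%), nutrient and metal families 1.32% (1.31% to 1.34%), and auxin families 1.28% (1.27% to 1.29%). The 2 families known for disease resistance genes, miR482 and miR2118, held 0.0501% (0.0477% to 0.0525%). Of 18 grapevine-specific families, 5 were listed, led by miR3623 with 138 reads, and they summed to 536 reads (0.0160%). Of the 52 families on the list fixed beforehand, 33 were in the profile. miR394, miR477, miR479, miR827, miR828 and miR858 were not in it, but it lists only 21-nt and 22-nt sequences. For a sequence of those lengths, a count of 0 allows up to 0.353 RPM, and it bounds no other length.

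Within families, 1 sequence usually led. TTTGGATTGAAGGGAGCTCTA made up 98.5% of miR159 (98.4% to 98.5%), and TCGCTTGGTGCAGGTCGGGAA made up 95.2% of miR168. miR166 was more mixed: TCGGACCAGGCTTCATTCCCC had 1953380 reads (74.9%) and TCTCGGACCAGGCTTCATTCC, whose 5' end differs, had 558805. In miR396 the leading sequences were TTCCACAGCTTTCTTGAACTT with 199979 reads and TTCCACAGCTTTCTTGAACTG with 51208. In miR167 the leading sequence was the 22-nt TGAAGCTGCCAGCATGATCTGG, with 56.2% of the family (55.7% to 56.7%). All 218 profile sequences were 21 or 22 nt long, and those of 21 nt held 99.0% of the reads.

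**Figure D1:**
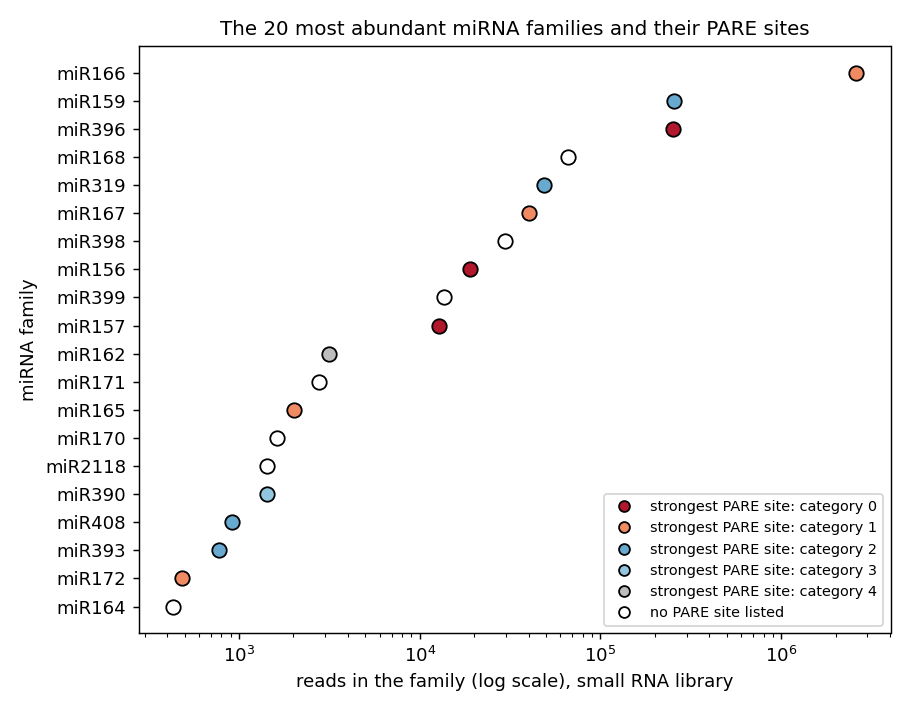
Reads in the small RNA library (log scale) for the 20 miRNA families with the most reads, coloured by the category of the strongest PARE site listed for each family. miR166 stands at 2606778 reads with a category 1 site, while miR168 (66445 reads) and miR398 (29504 reads) have no listed site.

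The authors' prediction from hairpins gave 317 miRNA loci with 255 distinct mature sequences. The most abundant sequence, the leading miR166 form, lay at 3 of the listed loci, on chromosomes 2, 5 and 7. A star sequence, the opposite strand of the hairpin, was reported only at the chromosome 2 locus, which runs from 2255856 to 2255876 on the plus strand, with 9568 star reads. The second miR166 form was placed on chromosome 8 from 3302809 to 3302829 on the minus strand, with 1373 star reads. miR159 had 1 locus, on chromosome 17 from 2609215 to 2609235. The miR396 forms lay on chromosome 11 (5246803 to 5246823 and 5253199 to 5253219) and chromosome 4 (5119668 to 5119688). miR168 lay on chromosome 2 from 17944902 to 17944922, with 3219 star reads, 4.84% of its mature and star reads together. miR319 had loci with 33591 reads on chromosomes 1 and 6, and miR398 a pair on chromosome 6 with 27755 reads each. A sequence with several genomic positions carries its full count at each, so the reads of these loci cannot be divided among them.

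Of the 317 loci, 188 had a mature sequence of 21 nt (59.3%, 53.7% to 64.8%), 73 of 20 nt and 56 of 22 nt. The loci lay on all 19 chromosomes, with 28 on chromosome 14 and 5 on chromosome 15, and 156 were on the plus strand (49.2%, 43.6% to 54.9%). Star sequences were reported for 28 loci (8.83%, 5.95% to 12.5%), and for 18.98% of loci with 10 reads or more. Many loci were weakly covered: 180 had under 10 reads (56.8%, 51.1% to 62.3%), which leaves 137 with 10 or more. Among known families, miR395 had the most loci (9), followed by miR171 (8), miR399 and miR403 (6 each).

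Loci whose mature sequence was identical to a profile sequence differed from the rest. These 63 known loci (19.9%, 15.6% to 24.7%), which fell into 21 families, had a median of 382 reads against 7 for the 254 unmatched loci. The profile lists only 21-nt and 22-nt sequences, so all 73 loci of 20 nt were unmatched by the rule itself. Among 10000 random sets of 63 loci, the central 95% of medians ran from 7 to 11 reads and none reached 382. Known hairpins were also more stable, with a median minimum free energy of -47.6 kcal/mol against -33.0 (random sets -40.0 to -32.5), and so was the energy per 100 nt, at -47.7 against -33.4. Their length did not stand apart, with medians of 95 nt and 96.5 nt (random sets 91 to 102 nt). Their GC content was at the upper end of the random sets, with medians of 47.6% and 44.5% (random sets 43.6% to 47.6%). A star was reported for 20 known loci (31.7%, 20.6% to 44.7%) and 8 unmatched ones (3.15%, 1.37% to 6.11%). The mature sequence began with T (U in the RNA) at 77.8% of known loci (65.5% to 87.3%) and 35.4% of unmatched loci (29.6% to 41.7%). The 63 known loci held 32 distinct mature sequences and the 254 unmatched loci 223, and loci that share a sequence are not independent. The intervals and random sets treat every locus as independent, so they may be too narrow. Among loci with a star, the median reads were 352.5 for known and 284.5 for unmatched loci, a ratio of 1.24. The 8 unmatched loci were 4 nested in profile sequences, with 520 to 20196 reads, and 4 others with 2 to 49.

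The 5 most abundant unmatched loci were all 20 nt long. TTGGACTGAAGGGAGCTCCC, on chromosome 17 from 3675989 to 3676008 on the minus strand, had 20483 reads and lay within miR319 sequences of the profile. TGACAGAAGAGAGTGAGCAC had 20196 reads and 3 loci, on chromosome 11 (7623290 to 7623309) and chromosome 4 (848278 to 848297 and 5357071 to 5357090), and lay within miR156 sequences. TTCCACAGCTTTCTTGAACT, on chromosome 9 from 7372605 to 7372624, had 3064 reads and lay within miR396 sequences.

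**Figure D2:**
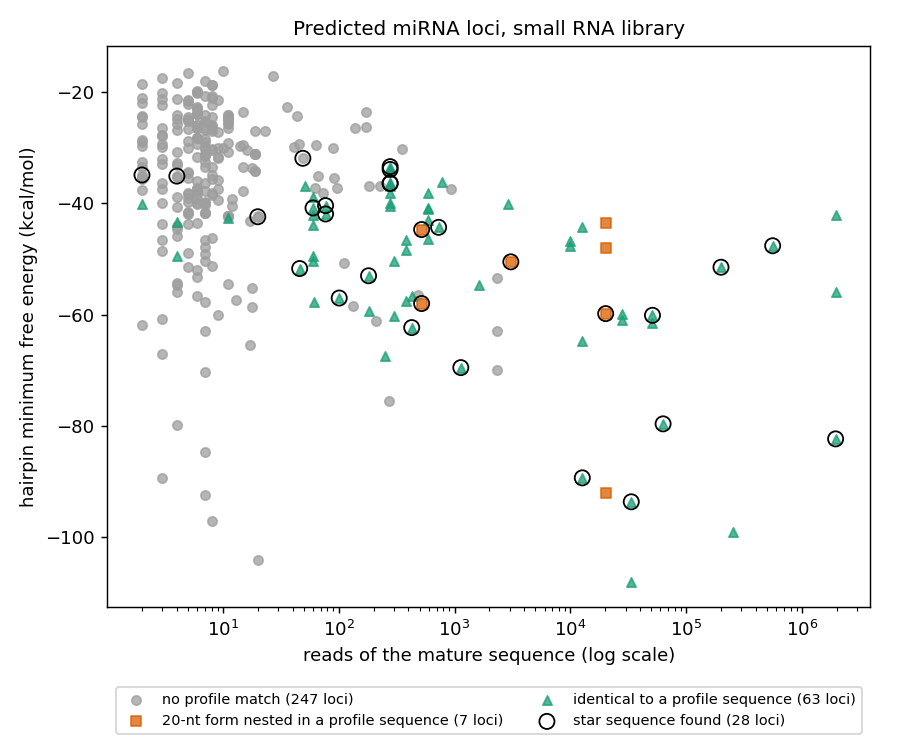
Each point is 1 of the 317 predicted loci, with the reads of its mature sequence (log scale) against the minimum free energy of its hairpin, by match to the profile, and circles mark the 28 loci with a star sequence. Known loci have a median of 382 reads, against 7 for unmatched loci, and the 7 loci with a 20-nt form nested in a profile sequence lie among the abundant ones.

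The PARE list paired small RNAs of any kind with transcript sites where uncapped 5' ends were read, at caller p-values of up to 0.1. How many of these sites reflect cleavage by the paired small RNA was not tested. The list held 51280 interactions of 45514 distinct small RNAs at 29847 sites in 4196 transcripts. Category 0, the strongest, had 3878 interactions (7.56%, 7.34% to 7.79%) at 1513 sites, 1 site in each of 1513 transcripts. Category 1 had 2212 sites, category 2 had 9637, category 3 had 1605 and category 4 had 14880 (49.9% of sites, 49.3% to 50.4%). Every category 4 site had a single read. The median was 3 reads per site in category 0 and 2 in category 1, and 105 category 0 sites had 10 reads or more.

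Small RNAs of 24 nt, the class known for transcriptional silencing of repeats, made up 30.6% of the distinct small RNAs in the list, and those of 21 nt 21.8%. Among 21-nt small RNAs 39.4% began with T, and among 24-nt ones 42.9% began with A. The shorter the small RNA, the larger was the share of its interactions in category 0. It was 17.5% at 19 nt (16.6% to 18.5%), 9.37% at 21 nt and 2.16% at 24 nt (1.93% to 2.39%). The listed records differed by length, however. Weak duplexes (an alignment score of 4 or more) made up 0.229% of category 4 interactions at 19 nt and 89.9% at 24 nt. In category 0 they made up 81.2% and 90.9%. The shares are thus taken over unlike records, and the trend may reflect which records the list kept.

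**Figure D3:**
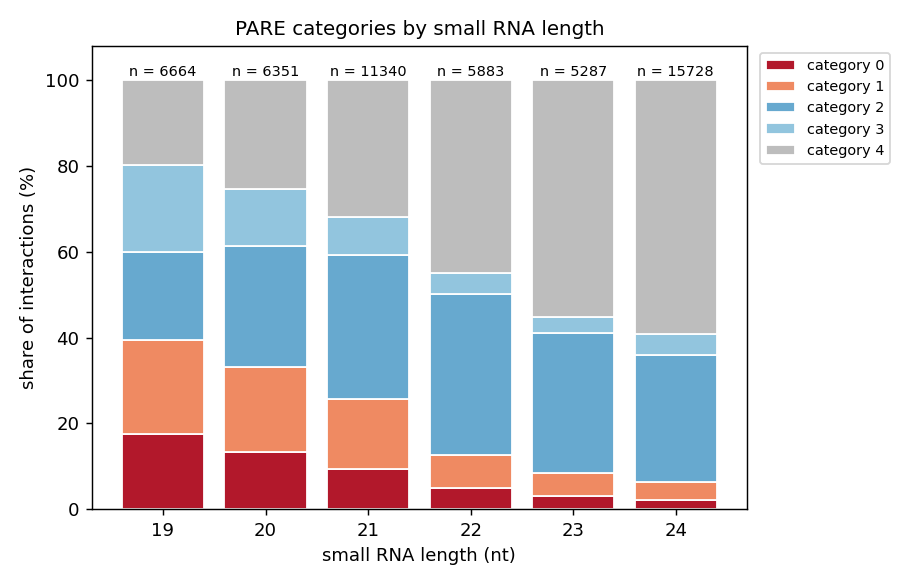
Share of PARE interactions in each category, by the length of the small RNA, with the number of interactions above each bar. Category 0 takes 17.5% of the interactions at 19 nt and 2.16% at 24 nt. Alignment scores of 4 or more make up 0.229% of category 4 interactions at 19 nt and 89.9% at 24 nt, so the shares are of unlike records.

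The category 0 sites with the most reads were not paired with profile miRNAs. The 15 highest, taken 1 per transcript, had 66 to 4272 reads and 65.3% of all reads at category 0 sites (64.6% to 66.0%). The small RNAs paired with them had at most 24 reads, with a median of 7, and 14 of the 15 duplexes had an alignment score of 4 or more, where lower is better. Such scores were general, at 81.9% of all category 0 interactions and at 67.7% to 83.6% of those in each other category. The highest was position 352 of transcript VIT_03s0038g02780.t01 on chromosome 3, with 4272 reads, a 19-nt small RNA of 6 reads and a score of 4.5. It was followed by position 1327 of a transcript on chromosome 12 (1698 reads) and position 587 of a transcript on chromosome 17 (1618 reads), both with a score of 4. Weighted by the authors for fragments shared between positions, the chromosome 3 and 12 sites had 2136 and 855 reads and the chromosome 17 site 1618. In 7 of the 15, the target sequence held at least 10 A in a row.

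Sites of profile miRNAs were few: 83 interactions (0.162%, 0.129% to 0.201%), at 32 sites in 32 transcripts, for 22 families. Of these sites 5 were in category 0 (15.6%, 5.28% to 32.8%), compared with 5.07% of all sites. Profile sequences are 21 or 22 nt, however, and at those lengths 7.44% and 4.12% of sites were in category 0. The 21-nt share lies within the interval of the profile sites. A score of at most 3 was found at 12 of the profile sites (37.5%, 21.1% to 56.3%). For sites of other small RNAs, of all lengths, the share was 14.5% (14.1% to 14.9%).

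Among the conserved families, 18 had a listed site, and 6 had one in category 0. miR156 and miR157 shared the site with the most reads, position 579 of VIT_10s0003g00050.t01 on chromosome 10. It had 16 reads, and TTGACAGAAGATAGAGAGCAC paired with the target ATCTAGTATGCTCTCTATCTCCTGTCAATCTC at a score of 2. The miR169 site, position 1513 of a transcript on chromosome 8, had 14 reads at a score of 3.5, from a family of 15 small RNA reads. miR160 had a category 0 site at position 686 of VIT_18s0001g04180.t01 on chromosome 18, with 10 reads. Its main sequence TGCCTGGCTCCCTGTATGCCA (382 reads) paired there with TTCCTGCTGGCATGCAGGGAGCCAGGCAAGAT at a score of 0.5. The miR396 site at position 504 of a transcript on chromosome 7 had 8 reads, and the miR397 site at position 674 of a transcript on chromosome 6 had 2, from a family of 16 reads.

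Category 1 was the strongest for miR165 and miR166, miR167 and miR172, each with 2 PARE reads. The site shared by miR165 and miR166 was position 593 of VIT_10s0003g04670.t01 on chromosome 10, with the target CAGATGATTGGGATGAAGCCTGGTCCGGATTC. The miR172 site was position 1315 of a transcript on chromosome 13, at a score of 1.5, and the miR167 site position 731 of a transcript on chromosome 16, at a score of 4. The best sites of miR159, miR319, miR393, miR408 and miR3623 were in category 2, that of miR390 in category 3, and those of miR162 and miR482 in category 4. Of these, miR408 had a score of 2.5, from a sequence of 191 reads. miR159, miR319 and miR393 scored 4, from sequences of 19, 6 and 2 reads, and miR390 scored 4.5, from 29 reads. miR3623, miR162 and miR482 scored 3.5, from sequences of 3, 5 and 18 reads. Of the 18 families with a site, 9 had a best site with a score of at most 3. How many families would have a listed site by chance was not tested. For 15 families of the list with reads in the profile no site was listed, among them miR168, miR398, miR399, miR171, miR170 and miR2118 each with at least 1421 reads. When small RNAs nested with a profile sequence were counted too, an alternative chosen after the data were seen, miR399 had 2 sites and miR2118 had 1. The list is filtered and incomplete, so a family without a listed site is not shown to lack one. Only 10 families had a site in categories 0 or 1, and 4 had one with 10 reads or more.

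Abundant families had somewhat more transcripts with a PARE site. Across the 53 families of the profile, which are not independent replicates, Spearman's rho between family reads and the number of transcripts with a site was 0.433. With category 0 sites alone rho was 0.150, but only 6 families had one, too few to judge by. miR166 with 2606778 reads had 2 sites and none in category 0, whereas miR160 with 409 reads had 4 sites, 1 of them in category 0. Families also differ in their number of profile sequences, with 24 for miR166 and 4 for miR160. A family with more sequences has more chances of a listed site, and rho was not adjusted for this.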

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

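The tests in this part were chosen after the result was seen. Predicted loci held 20-nt mature sequences, absent from the family profile, with 49138 reads. They made up 94.7% of the reads of all unmatched mature sequences. TTGGACTGAAGGGAGCTCCC (20483 reads) lay within miR319 sequences and TGACAGAAGAGAGTGAGCAC (20196 reads) within miR156 sequences. Most of these reads do not come from unrelated miRNAs, since 90.1% of the 20-nt reads lay within a listed sequence. By sequence it was 4 of 62, nearly all of the reads coming from these miR319 and miR156 forms, and the rest stay open. Why the profile left them out stays open: 0 of its 218 sequences were 20 nt long, which restates the pattern. From the profile alone, its length filter and a database without these forms cannot be told apart, and miRBase was not searched here. Adding them would raise miR156 from 18976 to 39172 reads, 2.06 times, and miR319 from 48618 to 69101. Another 20-nt sequence, TTGGCATTCTGTCCACCTCC, had 2328 reads and 3 loci and resembles miR394, a family known for an F-box target and not in the profile. No biological explanation was tested.

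The PARE list also held abundant small RNAs outside both the profile and the predicted loci. The most abundant was the 19-nt CCAAGATGAGTGCTCTCCT, with 27211 reads, over 2 differences from any profile sequence. Its listed category 0 site, position 262 of a transcript on chromosome 7, had 3 PARE reads, and 40 small RNA sequences were paired with that site. AACCAGGCTCTGATACCATGA (21 nt) had 14833 reads, with a category 4 site on chromosome 8. What kind of RNA these sequences come from, and whether they direct cleavage at the listed sites, was not tested.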

How the results depend on the processing

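No paired analysis was possible because each kind of library had 1 sample. Of 25 alternatives, 12 gave the same result and 13 moved it, and none reversed a sign, where the same means a count or ratio within 1.5 times, a share within its interval or a correlation within 0.1. 5 were chosen after seeing the data. The share of miR166 was 77.9% from the RPM column and with families of at least 10 counts. It was 58.4% for its leading sequence alone and 76.9% with nested 20-nt sequences added (chosen after seeing the data). The 317 loci were 255 as distinct sequences and 137 with at least 10 reads, and the length limit of 20 to 22 nt removed none. A star was reported for 8.83% of loci, 6.67% of distinct sequences and 18.98% of loci with at least 10 reads. The median reads of known over unmatched loci, 54.6 times, was 72.6 with distinct sequences, 67.6 with nested sequences counted as known (chosen after seeing the data) and 1.24 among loci with a star, where only 8 loci are unmatched. The 51280 interactions were 9855 in categories 0 and 1, 29847 as distinct sites, 16409 at a caller p of at most 0.01 and 1596 with at least 10 reads, since each filter removes records. They were 49704 without small RNAs within 2 differences of a profile sequence and 40931 with fragments of 1 position (both chosen after seeing the data). The 18 conserved families with a site were 10 in categories 0 and 1, 10 at a score of at most 3, 4 with at least 10 reads and 21 with nested small RNAs (chosen after seeing the data). The rank correlation (Spearman) between family reads and target transcripts was 0.433 with sites instead of transcripts, 0.400 without miR166 and 0.150 in category 0, where 6 families have a transcript.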

Other observations

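The tests of variants and of reads at crowded sites, and the search for VLQGQE, were fixed before their results were seen, and the other tests in this part were chosen after. A small RNA outside the profile had one of the best duplexes of category 0. TTCTTGACCTTGTAAGACCTT, with 1728 reads, paired at a score of 0.5 with position 1760 of a transcript on chromosome 6, which had 4 PARE reads and the target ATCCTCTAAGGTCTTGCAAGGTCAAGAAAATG. The sequence resembles tasiR-ARF, the small RNA made from TAS3 transcripts after miR390 cleavage, which is known to target ARF3 and ARF4. The peptide VLQGQE of those proteins was read in 1 of the 3 frames of the target. It lies within the paired stretch, so the duplex itself fixes it, and the search does not show what gene the site is in. The transcript has no name in the files.

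Peptides were read at the miRNA sites in the same way. Of 8 sites of miR166, miR172, miR160 and miR396 with a score of at most 3, 7 held the peptide of the textbook target class. These were GMKPGPD at the miR166 site, AASSGF at the miR172 site, GIQGAR or GMQGAR at 3 miR160 sites and RSRKPVE at 2 miR396 sites. These peptides are translations of the stretch that pairs with the miRNA, so a good duplex largely fixes them, and whether the sites lie in genes of those classes stays open. The exception was the miR396 site with the most reads, on chromosome 7 at position 504 (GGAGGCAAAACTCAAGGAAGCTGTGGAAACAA), where the peptide was absent. The category 0 site of miR156 did not encode ALSLLS in any frame, and a site outside the coding sequence would not.

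Some PARE sites were paired with very many small RNAs. The miR166 site on chromosome 10 had 775 small RNA sequences for 2 PARE reads, and the miR396 sites on chromosomes 7, 15 and 16 had 228, 205 and 90. The miR156 site had 97. By contrast, 66.6% of sites had 1 small RNA. These may be variants of an abundant miRNA: at these 5 sites 83.7% of the sequences (81.7% to 85.6%) had at most 2 differences from a profile sequence. Each of these sites pairs with a profile miRNA, however, and small RNAs that pair with the same target resemble each other, so the share does not settle their origin. The next crowded sites, with 41 and 40 small RNAs on chromosomes 6 and 7, had none within 2 differences of a profile sequence. The chromosome 6 site was led by the sequence that resembles tasiR-ARF, with 1728 reads, 44.4% of the small RNA reads there. At the chromosome 7 site the leading small RNA had 27211 reads, 98.3%. Neither leading sequence is in the profile, and only variants of profile sequences were counted. Whether these sites hold variants of their leading small RNA was therefore not tested. The sites after these were mixed. The share was 100% of 38 small RNAs at a miR167 site on chromosome 4. On chromosome 10 it was 0% of 30 at position 120 of a transcript. At position 983 of another, also paired with no profile sequence, it was 88.5% of 26. Over all sites but the 5 most crowded it was 0.818%. The variants at the miR166 site had a median of 3 reads, while TCGGACCAGGCTTCATTCCCC had 1953380, and whether they are sequencing errors or processing variants was not tested. Reads at the PARE site do not settle it, with a rho of 0.169 over all sites, and no biological explanation was tested.

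The category 0 sites with the most reads carried weak duplexes, as did most of category 0, where 81.9% of interactions had a score of 4 or more. In each other category the share was 67.7% to 83.6%. The p-value threshold of the list could let them in, but how the caller computes its p-value was not given in the sources used here. Among 19-nt small RNAs, 81.2% of category 0 interactions and 0.229% of category 4 interactions had a score of 4 or more, a gap of 80.9 percentage points, but at 24 nt the shares were 90.9% and 89.9%. Sites at a stretch of A are another candidate source, for 46.7% of the 15 named sites (21.3% to 73.4%) had 10 A in a row in the target, against 0.597% of category 0 sites and 8.65% of those with 10 reads or more. The stretches were noticed in these same 15 sites, which are part of that last group. Among the named sites without such a stretch, position 407 of a transcript on chromosome 7 (114 reads) stands apart. Its target begins with the 3' part of a miR408 profile sequence itself, not its complement, and a predicted miR408 locus lies on chromosome 7. Whether this transcript is a miR408 precursor was not tested, so its reads cannot be taken as cleavage by the paired small RNA. The other sites without such a stretch remain open, and no biological explanation was tested.

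Unmatched loci with a star sequence numbered 8. Sequences nested in profile miRNAs made up 50% of them (15.7% to 84.3%): miR156 on chromosome 4, miR396 on chromosome 9, and miR167 on chromosomes 5 and 14. The share did not pass the bound of over 50% set for shortened forms, but a share of loci cannot show what the nested loci are. Whether they are shortened forms stays open, and the miR156 form had 20196 reads against 1716 for the 21-nt TTGACAGAAGAGAGTGAGCAC. Transfer RNA fragments may account for a further 25% (3.19% to 65.1%), on chromosomes 10 and 14, whose hairpins held the B box, the internal promoter of transfer RNA genes. Among all 254 unmatched hairpins 8 had the box, and at most 5 did in any of 100 shuffled sets. The box was also in 1 of the 63 known hairpins (1.59%, 0.0402% to 8.53%), of miR171, so the box alone does not settle it. The other 2 loci, on chromosome 19 from 18872731 to 18872751 and chromosome 6 from 19950755 to 19950775, had 4 and 2 mature reads and 6 star reads each.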
